A study of Mus musculus with 6 samples.

How the data were processed

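ATAC-seq libraries of mouse brown adipocytes (WT-1 line) in 3 groups of 2, vehicle control, stimulated control and stimulated H2A.Z knockdown, were analysed from the deposited peak lists. Each list gives the position, centre, width, total signal, height and height_logP of the peaks of 1 library, in steps of 10 bp, on the mm10 build. The authors' notes name the build and deepTools 3.3.1; the aligner, the peak caller and the filters are not given in the sources used here. Per the file headers, total signal and height are in units of signal, the sequencing signal summed over or at the top of a peak. Every height was a whole multiple (within 0.01 of a step) of a step specific to its library, and the relation of height to height_logP was the same in all 6, so the deposited signal had been scaled by the authors to a common genome-wide mean. Per the file headers, height_logP is a −log10 p-value, and it matched the upper tail of a Poisson distribution with 1 mean for all 6 libraries. Per the file headers, width_above_cutoff is a length in bp above the authors' height limit. Heights printed are the authors' values. Depth is known only relative to the other libraries, from the step: the lowest reported heights, about 16 in each library, equal 12 steps in vehicle control replicate 2 and 27 to 35 in the others, so heights there are coarser.

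Peaks on chromosomes 1 to 19, X and Y of all 6 libraries were merged into 98129 regions when they overlapped by at least 1 bp, and a library held a region when 1 of its peaks overlapped it. Mitochondrial peaks were kept out of the regions and given as a share of the signal in peaks. A region was gained (lost) when both libraries of a group and neither of the other held (lacked) it. Counts were set beside 100 randomised tables that kept the number of regions per library and of libraries per region. They were made by 300 trades between pairs of all 6 libraries with seed 1. These tests are one-sided and take regions, not libraries, as the units. Numbers of peaks were compared by two-sided exact permutation. Location used 3 classes: within 1 kb of either end of a gene, inside a gene, or between genes, from gene extents of the RefSeq annotation of GRCm38.p6 (21027 protein-coding genes). The annotation used here has no strand or exons, so either gene end stands for the transcription start, and exons and introns were not separated. Each region was assigned to the gene with the nearest end within 50 kb. The 10 tallest regions of each gained or lost set were named by the nearest gene at any distance. Gained and lost regions were compared with the regions held by all 4 libraries (location) or with all other regions held by both libraries of the same group (gene lists), by an exact Cochran-Mantel-Haenszel test, two-sided, over 10 strata of mean height rank, and Benjamini-Hochberg adjustment over 12 location tests and 60 list tests. Intervals are 95%.

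The 15 gene lists (273 genes matched, 2 names unmatched) were thermogenic and brown identity, cAMP early response, beta-adrenergic signalling and lipolysis, fatty acid and glucose uptake and oxidation, lipogenesis and creatine cycling, white and general adipocyte, preadipocyte and fibroblast, skeletal muscle, immune cell, interferon response, p53 and stress, cell cycle, H2A.Z with chaperones and chromatin architecture, circadian and nuclear receptor, and housekeeping. The white and general adipocyte list shares Pparg and Cebpa with the thermogenic list and Plin1 and Fabp4 with the beta-adrenergic list. The lists, the comparisons by presence, their tests and their alternatives (equal list lengths, the taller 29706 peaks of each library, 50% coverage, merging within 200 bp, autosomes only, no strata, gained against lost regions, 2.5 kb, 10 kb and 100 kb windows, the replicate block and leaving out each library) were fixed before the data were examined. So was a rule for genes named from those sets: the 10 tallest regions of each set, up to 12 genes of the thermogenic, cAMP and beta-adrenergic lists per set, and a short list of fixed genes such as Ucp1, Ppargc1a, Pnpla2, H2az1 and Actb.

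The comparison of heights was chosen after the columns of the lists had been seen, since scores had been assumed not to be comparable between libraries. log2 heights of the 47471 regions with a peak in all 6 libraries were centred on each library's median (shifts of −0.58 for vehicle control replicate 2 and 0.21 for stimulated control replicate 2, the largest) and fitted with limma 3.58.1 (trend on, moderated two-sided test, Benjamini-Hochberg over regions, threshold 0.05). A region that lacks a peak in 1 library is not in this test. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over 30 lists and comparisons. Each list gene was also counted once, by the mean of its regions, against 100000 random lists matched on the number of regions per gene, up to 8 (two-sided permutation test). These tests treat regions or genes as nearly independent. Genes named by height were those of the 10 largest called rises and falls on stimulation, the largest called rise and fall of up to 12 genes of each of 4 lists, the gene-end regions of the fixed genes, the 10 smallest p-values with knockdown, the largest change with knockdown of up to 12 genes of the thermogenic, interferon and circadian lists, and all regions nearest to Ucp1.

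Alternatives chosen after seeing the data were heights as deposited, quantile and loess normalisation, the replicate block, absent peaks set to 16, leaving out each library, regions of mean height above 64, only the 4 libraries compared, an estimated correlation, genes as the unit, a second interferon list that shares no gene with the first, peaks of at least 32 in height with and without vehicle control replicate 2, and comparisons of 1 library with 1. Replicate numbers were not used to pair samples, since the labels do not say that they do; with 2 pairs, differences from the group mean correlated at 0.0628, 0.0597 and 0.251 between groups. Recovery was tested on heights simulated from each region's mean and replicate differences shuffled among regions of like height, with changes added to 50 regions per size. The randomisation and the exact test were checked on simulated data. Motif searches were not run, as no genome sequence was used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.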

Results

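Chromatin accessibility was measured by ATAC-seq, which inserts sequencing adapters into open DNA, in differentiated brown adipocytes of the mouse WT-1 preadipocyte line. The cells carried a lentiviral non-targeting shRNA or an shRNA against the histone variant H2A.Z from day 6 of differentiation, and were harvested on day 11 after 4 h with vehicle or 1 µM CL316,243, an agonist of the beta3-adrenergic receptor. The 3 groups were vehicle control, stimulated control and stimulated H2A.Z knockdown, with 2 libraries each. The deposited values are peak lists, one per library, with a height for each peak. Vehicle control replicates 1 and 2 held 74609 and 59412 nuclear peaks, stimulated control replicates 1 and 2 held 74509 and 81023, and stimulated H2A.Z knockdown replicates 1 and 2 held 80667 and 78926. Read counts are not given in the sources used here. The step between possible heights, which falls as a library gets deeper, put vehicle control replicate 2 lowest. The steps of the other libraries, in the order above, were 0.588, 0.571, 0.471, 0.597 and 0.471, so each was at least 2.31 times as deep. Vehicle control replicate 2 also had 23.0% of its signal in peaks on the mitochondrial genome, where the other libraries had 6.56% to 7.63%. Group means were 67010.5 ± 10745.9 peaks (SD, n = 2) for vehicle control, 77766 ± 4606 for stimulated control and 79796.5 ± 1231 for stimulated H2A.Z knockdown. A two-sided exact permutation test of 2 libraries against 2 cannot give a p below 0.333; it gave 0.667 for stimulated against vehicle control and 1 for knockdown against stimulated control. Heights are given as group means ± SD with n = 2, and adjusted p-values without another tool named come from limma. These p-values measure only the spread between these samples, since the labels do not say whether the replicates were separate cultures.

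Stimulated against vehicle control addresses how the accessible chromatin of brown adipocytes changes within hours of a thermogenic stimulus. The largest rise of all regions tested lay at the start of Ucp1, the mitochondrial uncoupling protein that makes heat in brown fat. The peak from 83290020 to 83291130 on chromosome 8 (mm10) went from a height of 25.5 ± 8.77 in vehicle control to 303.3 ± 54.2 in stimulated control, a 9.22-fold rise after centring (log2 change 3.21, SE 0.18, adjusted p = 3.93e-10). The 3 other regions nearest to Ucp1 that had a peak in all 6 libraries, 2.32 to 5.71 kb upstream, rose as well, by log2 changes of 0.91, 1.51 and 1.02. A region inside Ppargc1a, which encodes the PGC-1alpha coactivator of mitochondrial biogenesis, rose from 20.9 ± 0.315 to 189.5 ± 6.64 (chromosome 5, 51545250 to 51546240; log2 change 2.78, SE 0.21, adjusted p = 1.2e-08). The region at the high-coordinate end of the annotated extent of Ppargc1a stood at 38.2 ± 15 and 55.6 ± 6.73 and did not pass (log2 change 0.20, SE 0.24, adjusted p = 0.603). That extent runs from 51454249 to 52115853, and transcription starts inside it could not be told from the gene extents used.

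**Figure D1:**
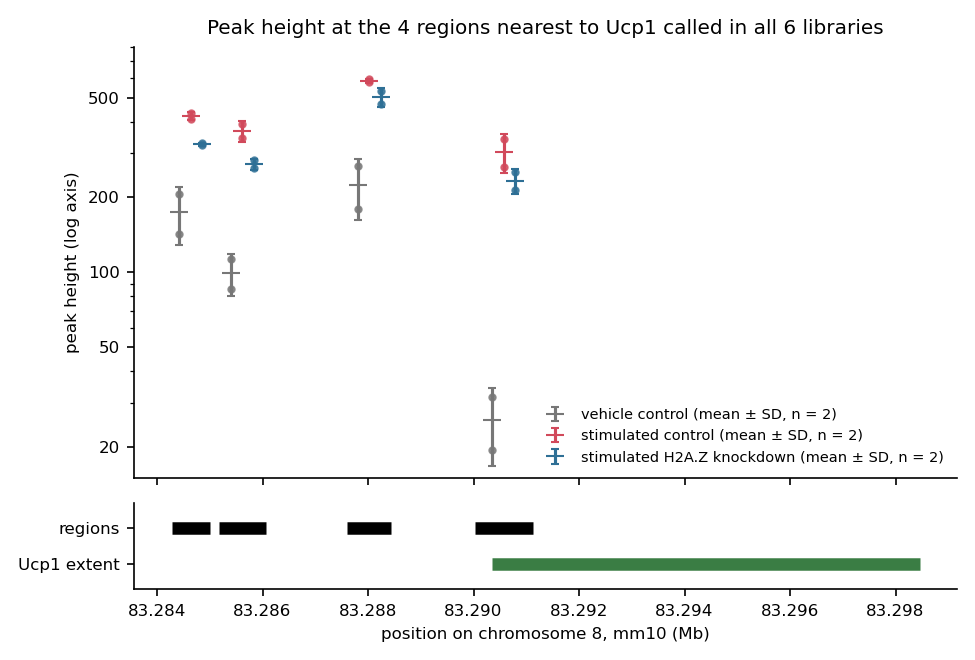
Peak height (log axis, authors' units) in each of the 6 libraries at the 4 regions nearest to Ucp1 with a peak in every library, with the mean and SD of each group (n = 2), above a map of the regions and of Ucp1 on chromosome 8. At the region over the start of the gene the mean height was 25.5 in vehicle control, 303.3 in stimulated control and 232.8 in stimulated H2A.Z knockdown.

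The 10 largest rises also included regions nearest to Ccdc91 (log2 change 2.96), Alkbh3, a DNA repair demethylase (2.60), Chd1, a chromatin remodeller (2.57), Cecr2 (2.48), Ptges, which makes prostaglandin E2 (2.44), and Uck2, a uridine kinase (2.43). The remaining members of those 10 had no gene within 50 kb, at log2 changes of 2.51 and 2.45. The largest fall lay inside Thra, the gene of thyroid hormone receptor alpha, where the height went from 428.6 ± 4.72 to 92.6 ± 9.02 (chromosome 11, 98750340 to 98751650; log2 change −2.61, SE 0.18, adjusted p = 3.57e-09). Other large falls lay at Mgat5b, a glycosyltransferase (−2.23), Phc2, a Polycomb subunit (−2.19), Klra10 (−2.18), Sdk2, a cell adhesion molecule (−2.13), and Nfix, a transcription factor (−2.12), besides 1700029H14Rik (−2.31). Of the 47471 regions with a peak in all 6 libraries, 4275 rose and 6115 fell at an adjusted p below 0.05, and 16187 had an unadjusted p below 0.05. Changes of more than 2-fold numbered 1530 among the rises and 1650 among the falls, or 3901 and 338 with the heights as deposited.

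The share of the called regions that rose depended on how the libraries were scaled, since the median change of all regions was −0.12 after centring and 0.27 with the heights as deposited. It was 41.1% after centring and 91.0% with the heights as deposited (4618 higher, 454 lower). Loess normalisation gave 53.1% (4997 and 4418), quantile normalisation 52.2% (5089 and 4669) and regions of mean height above 64 gave 51.3%. After centring, vehicle control replicate 1 minus replicate 2 had a median of −0.29 in regions that fell, 0.010 in those that rose and −0.073 in the others. The vehicle heights of regions that fell were thus higher in replicate 2. A tested region had to have a peak in that library too, and centring raised its log2 heights by 0.58. How far this adds to the falls was not tested. Without vehicle control replicate 2, the shallow library with 23.0% mitochondrial signal, 6165 regions rose and 4714 fell (56.7% higher). Leaving out vehicle control replicate 1 gave 6486 rises and 11329 falls, leaving out stimulated control replicate 1 gave 1798 and 1868, and leaving out stimulated control replicate 2 gave 2514 and 2724. The rises at Ucp1, Ppargc1a, Ccdc91, Alkbh3, Chd1, Cecr2, Ptges and Uck2 and the falls at Thra, Mgat5b, Phc2, Klra10, Sdk2, Nfix and 1700029H14Rik kept their direction and passed under every setting run on peak height.

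Genes of the early cAMP response, the transcripts that beta-adrenergic signalling switches on first, had 20 regions that rose and 13 that fell among 133, with a rise at 15 of its 26 genes and a fall at 9. Fosl1, an AP-1 subunit, rose from 34.7 ± 19.8 to 209.7 ± 15.2 at its gene end (log2 change 2.32, SE 0.19, adjusted p = 3.97e-08). Fosl2, of the same family, rose by 2.11 at a region 34.6 kb away, and a region inside Nr4a1, an orphan nuclear receptor induced by cAMP, rose by 1.25. Regions nearest to Klf9 (1.98), Ier3 (1.94), Jun (1.81), the clock gene Per1 (1.55), Atf3 (1.48), Gadd45g (1.42), the kinase gene Sik1 (1.31), the phosphatase gene Dusp1 (1.16) and the phosphodiesterase gene Pde4b (1.07) rose too. Other regions nearest to Jun (−1.18), Ier3 (−0.84), Sik1 (−0.76), Klf9 (−0.75) and Dusp1 (−0.61) fell, as did regions nearest to Crtc3, a CREB coactivator (−1.07), Fos (−0.99), Fosb (−0.73) and Rgs2 (−0.53). With the heights as deposited these 9 falls stayed below 0, and none passed. Crtc3 and Klf9 passed with any 1 library left out, and the others did not. Without stimulated control replicate 1 the values were −1.08 at Jun, −0.87 at Ier3, −0.66 at Sik1, −0.55 at Dusp1, −1.11 at Fos, −0.82 at Fosb and −0.44 at Rgs2. Without stimulated control replicate 2 all of these but Dusp1 failed as well (−1.26 to −0.61). So did Jun, Fos, Fosb and Rgs2 without vehicle control replicate 2 (−0.74 to −0.22), Ier3 and Sik1 without vehicle control replicate 1 (−0.67 and −0.68), and Sik1 without either knockdown library (−0.74 and −0.75). Fos (−0.87 and −0.68), Ier3 (−0.78 and −0.64) and Rgs2 (−0.41 and −0.45) failed after quantile and after loess normalisation too, and Sik1 after loess (−0.64). The regions at the gene ends of Nr4a1, Fos, Crem and Per1 did not pass, with log2 changes of 0.22, 0.22, −0.12 and −0.28, of which those of Crem and Per1 turned positive with the heights as deposited and passed as falls without vehicle control replicate 1 (−0.35, adjusted p = 0.0279, and −0.53, adjusted p = 0.00107). The list as a whole stood above other regions in camera (mean 0.08, median −0.02, adjusted p = 0.0368), so its median differs in sign from its mean. The call ended with an estimated correlation (adjusted p = 0.987) and without vehicle control replicate 1 (adjusted p = 0.0512). The sign of the median depended on scaling, at 0.38 with the heights as deposited, 0.12 after quantile and 0.098 after loess normalisation, and 0.029 with absent peaks set to 16. It was also above 0 among regions of mean height above 64 (0.12) and without vehicle control replicate 2 (0.052), stimulated control replicate 2 (0.015) or knockdown replicate 1 (0.00020). Adjusted over the list alone, 20 regions rose and 13 fell.

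Beta-adrenergic signalling and lipolysis genes had 22 rising and 4 falling regions among 121, also 22 and 4 adjusted over the list alone, with a rise at 10 of 22 genes and a fall at 4. The region inside Adcy3, the adenylyl cyclase linked to thermogenic adipocytes, rose from 84.9 ± 14.6 to 524.7 ± 24.7 (log2 change 2.24, SE 0.14, adjusted p = 1.62e-09). Rises followed at Abhd5, the coactivator of adipose triglyceride lipase (1.83), Prkar2b, a regulatory subunit of protein kinase A (1.71), the lipid droplet gene Plin2 (1.31) and Mgll, monoacylglycerol lipase (0.65). Gnas, which encodes the stimulatory G protein subunit, held a region that fell from 432.2 ± 70.3 to 200.4 ± 12.7 (log2 change −1.50, SE 0.14, adjusted p = 1.95e-07). Falls were also called at another region of Mgll (−1.11), larger than its rise, and at the protein kinase A genes Prkar1a (−0.97) and Prkaca (−0.89). With the heights as deposited these 3 read −0.71, −0.58 and −0.49 and did not pass. Without stimulated control replicate 2 Prkar1a (−0.92) and Prkaca (−0.65) did not pass, nor did Prkaca without stimulated control replicate 1 (−1.11). Of the 10 genes with a rise, 5 lost it without stimulated control replicate 1: Fabp4 (0.98, then 0.85), Adrb1 (0.67, then 0.64), G0s2 (0.66, then 0.67), Plin5 (0.59, then 0.43) and Hcar2 (0.49, then 0.34). Without stimulated control replicate 2 Adrb1 (0.72), G0s2 (0.66) and Hcar2 (0.65) failed, without vehicle control replicate 2 Adrb1 (0.41), and with the heights as deposited Plin5 (0.98) and Hcar2 (0.89). Hcar2 also failed without vehicle control replicate 1 (0.36) or either knockdown library (0.51 and 0.50), after loess normalisation (0.51) and with only the 4 libraries compared (0.50). The gene-end regions of Pnpla2, adipose triglyceride lipase, and of Adrb3, the receptor itself, did not pass at −0.31 and −0.44. Both passed as falls without vehicle control replicate 1 (−0.47, adjusted p = 0.00256, and −0.69, adjusted p = 0.00923), and that of Pnpla2 turned positive with the heights as deposited. In camera the list stood above other regions (median 0.07, adjusted p = 0.00155; adjusted p = 0.987 with an estimated correlation). That median was 0.47 with the heights as deposited, 0.21 after loess and 0.18 after quantile normalisation, 0.12 with absent peaks set to 16 and 0.17 among regions of mean height above 64. It was 0.020 without vehicle control replicate 1, 0.21 without vehicle control replicate 2 and 0.11 without stimulated control replicate 2.

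Among genes of fatty acid and glucose uptake and oxidation, 34 regions rose and 10 fell of 129, with a rise at 14 of 19 genes and a fall at 7; adjusted over the list alone, 38 rose and 13 fell. Hadha and Hadhb, the subunits of the mitochondrial trifunctional protein of beta-oxidation, rose by 1.83 and 1.33. Acadm, medium-chain acyl-CoA dehydrogenase, rose by 1.73, lipoprotein lipase gene Lpl by 1.39, glucose transporter gene Slc2a1 by 1.30 and the carnitine palmitoyltransferase gene Cpt2 by 1.03. At Cpt2 the height went from 125.3 ± 40.5 to 327.7 ± 24 (SE of the log2 change 0.13, adjusted p = 1.02e-05). Other regions fell at Cpt2 (−1.13, larger than its rise), Lpl (−0.61) and Slc2a1 (−0.57), and at Acsl1 (−1.16), Pfkfb3 (−1.09), Acsl5 (−0.96) and Hk2 (−0.89). With the heights as deposited these 7 falls ranged from −0.76 to −0.18, and none passed. Without stimulated control replicate 1 the falls at Cpt2 (−0.97), Lpl (−0.54), Slc2a1 (−0.64) and Acsl5 (−0.80) did not pass. The same held without stimulated control replicate 2 for Lpl (−0.67), Slc2a1 (−0.50) and Acsl5 (−1.10), and without vehicle control replicate 2 for Lpl (−0.27) and Acsl5 (−0.59). Lpl also failed after quantile (−0.39) and Acsl5 after loess normalisation (−0.89). Rises called at Acsl1 (1.09), Cd36 (1.00), Pfkfb3 (0.79), Pdk4 (0.72) and Cpt1a (0.66) ended without stimulated control replicate 1 (0.90, 0.84, 0.68, 0.60 and 0.57). That of Pfkfb3 ended as well without stimulated control replicate 2 (0.90) or vehicle control replicate 2 (0.63). Camera put the list above other regions (median 0.12, adjusted p = 0.000692; adjusted p = 0.987 with an estimated correlation). The median was 0.52 with the heights as deposited, 0.23 after quantile or loess normalisation and 0.19 among regions of mean height above 64. It was 0.22 without vehicle control replicate 2, 0.068 without stimulated control replicate 1 and 0.18 without stimulated control replicate 2.

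Thermogenic and brown identity genes moved both ways, with 21 regions that rose and 23 that fell among 140 (22 and 24 adjusted over the list alone), at 12 and 9 of 22 genes. The list did not differ from other regions in camera (median −0.05, adjusted p = 0.496). Besides Ucp1, rises were called at Ppargc1b, a relative of PGC-1alpha (1.84), Gk, glycerol kinase (1.48), Kcnk3, a potassium channel (1.04), Cox7a1, a cytochrome oxidase subunit (0.81), and Cidea, a lipid droplet protein (0.72). Other regions nearest to Pparg, the master regulator of adipocyte differentiation, and to Ppara, a receptor that drives fatty acid oxidation, fell, with log2 changes of −1.46 and −1.15, while rises at further regions of both were called at 0.53 and 0.76. Kcnk3 and Cidea likewise held regions that fell (−0.77 and −0.71). With the heights as deposited 7 of the 9 genes with a fall lost it, namely Cebpa (−1.14, then −0.74), Cebpb (−1.01, then −0.62), Esrrg (−0.93, then −0.54), Acot11 (−0.89, then −0.50), Kcnk3 (then −0.37), Cidea (then −0.32) and Cox8b (−0.46, then −0.07). Rises were also called at Cpt1b (0.86), Cebpa (0.63), Bmp8b (0.61) and Elovl3 (0.54). Calls that ended without stimulated control replicate 1 were the rises at Pparg (0.55), Ppara (0.66), Cpt1b (0.67), Bmp8b (0.57) and Elovl3 (0.54) and the falls at Cebpa (−0.87), Esrrg (−0.68) and Cox8b (−0.44). Without stimulated control replicate 2 they were the rises at Pparg (0.52), Ppara (0.87), Cpt1b (1.06) and Elovl3 (0.55, or 0.94 as deposited) and the falls at Cidea (−0.50), Acot11 (−0.82) and Cox8b (−0.47). The rises at Ppara (0.57) and Elovl3 (0.35) ended without vehicle control replicate 1, and the rise at Cpt1b (0.39) and the fall at Cebpa (−0.56) without vehicle control replicate 2. Cox8b failed also without either knockdown library (−0.44 and −0.45), after quantile (−0.40) or loess normalisation (−0.43) and above a mean height of 64 (−0.41). The median of the list was 0.34 with the heights as deposited and 0.06 after quantile or loess normalisation. With each gene counted once, by the mean of its regions, fatty acid and glucose genes had a mean change of 0.18, with 14 of 19 genes above 0. The cAMP list had 0.14 (17 of 26), beta-adrenergic genes 0.13 (14 of 22) and thermogenic genes 0.08 (13 of 22). A two-sided permutation test against 100000 random gene lists gave adjusted p-values of 0.0021, 0.0024, 0.00576 and 0.0225. That test takes genes as independent, and in camera with an estimated correlation each of these 4 lists had an adjusted p = 0.987. Adjustment gave every list and comparison this same value in that setting. The unadjusted camera p-values were 0.145 for fatty acid and glucose, 0.152 for cAMP, 0.225 for beta-adrenergic and 0.598 for thermogenic genes.

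**Figure D2:**
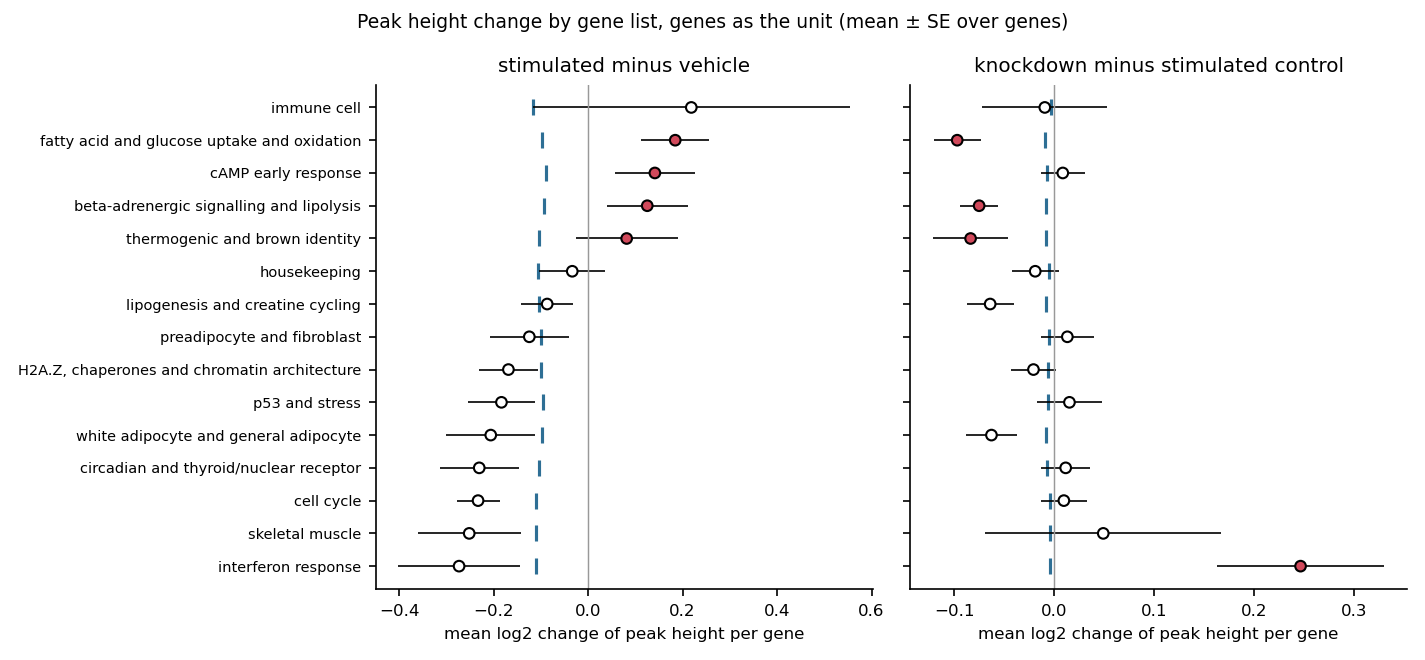
Mean log2 change in peak height per gene list, each gene counted once (points, mean; bars, SE over genes), for stimulated minus vehicle control and for knockdown minus stimulated control; the ticks mark the mean of random gene lists and filled red points an adjusted p below 0.05. The interferon list stands apart with knockdown at 0.25, and the fatty acid and glucose list has the highest called mean on stimulation at 0.18.

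The 11 other lists fixed beforehand did not pass camera on stimulation. White and general adipocyte genes had 16 rising and 27 falling regions of 120 (median −0.15, adjusted p = 0.958; 21 and 32 adjusted over the list alone). Lipogenesis and creatine cycling genes had 13 and 20 of 103 (median −0.14, adjusted p = 0.968; 15 and 22). Circadian and nuclear receptor genes had 5 and 19 of 101 (median −0.20, adjusted p = 0.166; 8 and 23). For cell cycle genes limma called 0 rises and 6 falls of 37 (median −0.26, adjusted p = 0.0778; 0 and 5). Genes of p53 and stress had 5 and 10 of 49 (median −0.15, adjusted p = 0.862; 5 and 10). H2A.Z, chaperone and chromatin architecture genes had 1 and 6 of 55 (median −0.17, adjusted p = 0.958; 1 and 2), and preadipocyte and fibroblast genes 3 and 4 of 52 (median −0.11, adjusted p = 0.958; 3 and 3). Interferon genes had 2 and 2 of 27 (median −0.14, adjusted p = 0.958; 2 and 2), and skeletal muscle genes 0 and 2 of 12 (median −0.16, adjusted p = 0.951; 0 and 1). Immune cell genes had 1 and 0 of 7 (median 0.30, adjusted p = 0.190; 1 and 0) and housekeeping genes 1 and 2 of 44 (median −0.17, adjusted p = 0.968; 1 and 1). The gene-end regions of H2az1, H2az2 and Actb did not pass at −0.30, −0.21 and −0.19, values that turned positive with the heights as deposited, while H2az1 passed as a fall without vehicle control replicate 1 (−0.45, adjusted p = 0.00445). With the heights as deposited the median of each of the 10 lists below 0 in this group also turned positive, to between 0.14 for cell cycle and 0.29 for preadipocyte and fibroblast genes. Without vehicle control replicate 2 the immune cell list passed (median 0.34, adjusted p = 0.0301).

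By the presence of peaks alone, 6861 regions were gained on stimulation, with a peak in both stimulated control libraries and in neither vehicle control library, and 1136 were lost. The tallest gained region lay inside Mylk, myosin light chain kinase (chromosome 16, 34986310 to 34986910), with heights of 257.6 and 228.2 in the stimulated control libraries. Dnaja4, a heat shock co-chaperone, followed with 190.8 and 202.7, and then Scp2, a sterol carrier protein, Cdc42bpa, Ints10, Ptpa, Fam110c, Gmpr, Tcim and Cib4. Gained regions near list genes included Plin2, 0.638 kb from its end (42.8 and 42.0), Lipe, hormone-sensitive lipase (20.0 and 20.3), and Fgf21, a hormone secreted by stimulated brown fat (16.6 and 17.9). The peaks at Lipe and Fgf21 were close to the lowest reported height of about 16, so their absence in vehicle control may reflect that limit. A neighbouring region of Lipe had a peak in vehicle control replicate 1 as well (17.6, against 20.0 and 21.2 in stimulated control). The tallest lost region was nearest to Wdr75, 71.5 kb away, at 69.9 and 58.0 in vehicle control. Others were nearest to Colec11, Rgs3 (52.0 kb away), the receptor tyrosine kinase gene Fgfr1 and Prdm16, a brown fat transcription regulator. Gained regions outnumbered those of 100 randomised tables with the same library and region totals (4008 ± 45.9, a ratio of 1.71), as did lost ones (316.5 ± 17.4). In each one-sided permutation test p was 0.0099, the smallest these permutations can give. Without the shallow vehicle control replicate 2, gained and lost regions numbered 7615 and 5684, a ratio of 1.34 in place of 6.04. The counts were 18675 and 3429 without vehicle control replicate 1, 12852 and 1500 without stimulated control replicate 1, and 9735 and 2775 without stimulated control replicate 2; each asks fewer libraries to match. Regions at least 32 high in both libraries that held them numbered 897 gained and 17 lost, 4189 and 108 without vehicle control replicate 1, and 1021 and 140 without vehicle control replicate 2.

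**Figure D3:**
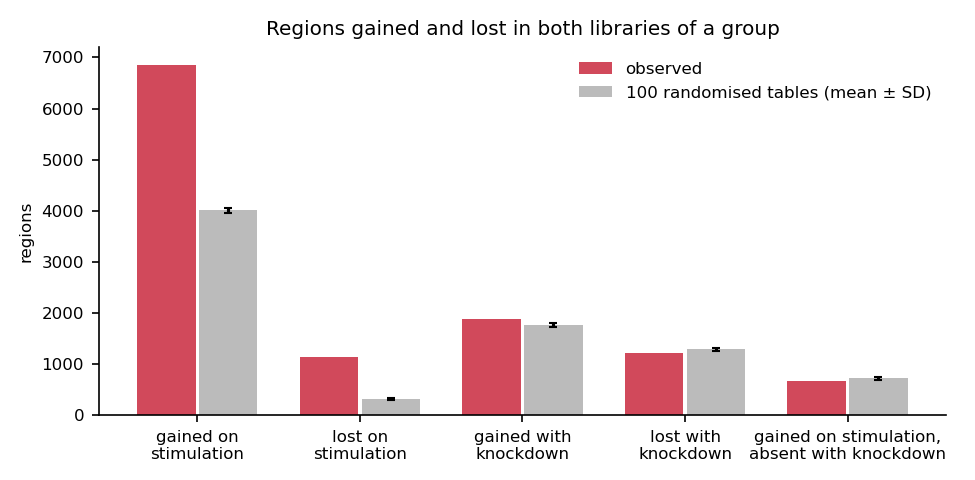
Number of regions gained and lost in each comparison, and gained on stimulation then absent with knockdown, in the data and in 100 randomised tables (mean and SD; bars start at 0). The stimulation sets lie above the randomised tables (6861 against 4008 gained) and the knockdown sets close to them (1875 against 1764 gained).

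Gained regions were enriched near genes of 3 lists. Those nearest to fatty acid and glucose genes numbered 45, at 13 of 19 genes, an odds ratio of 3.54 (95% interval 2.27 to 5.51, adjusted p = 3.80e-06, two-sided exact test over height strata). Beta-adrenergic and lipolysis genes had 34 at 13 of 22 genes (odds ratio 2.56, 1.64 to 4.00, adjusted p = 0.00139) and early cAMP genes 27 at 15 of 26 genes (2.71, 1.62 to 4.54, adjusted p = 0.00594). The exact test counts regions as independent, although several lay at the same gene, so its intervals and p-values may be too narrow. Thermogenic genes had 26 gained regions at 15 of 24 genes, among them Kcnk3, Cebpb, Esrrg, Elovl3 and Fgf21, and did not pass (odds ratio 1.51, adjusted p = 0.439), although they did without stimulated control replicate 2 (1.87, adjusted p = 0.0137). Over all alternatives their adjusted p ran from 0.000387 to 0.962. Without vehicle control replicate 1 the fatty acid and glucose list gave 1.88 (adjusted p = 0.0958) and the cAMP list 1.66 (adjusted p = 0.222). Set against lost regions none of these lists passed. The odds ratios were 3.74 for fatty acid and glucose, 5.65 for beta-adrenergic and 4.48 for cAMP genes, with 2, 1 and 1 lost regions. The cAMP call also ended without strata (1.55, adjusted p = 0.394), with equal lists (2.41), with merged peaks (2.48) and with genes within 10 kb (2.49). The beta-adrenergic call also ended without strata (1.85, adjusted p = 0.0600) and within 10 kb (2.48, adjusted p = 0.0540). Calls not made with all libraries appeared for lipogenesis genes without vehicle control replicate 1 (2.5, adjusted p = 0.00373) and for housekeeping genes without stimulated control replicate 2 (3.42, adjusted p = 0.0137). Over all alternatives the adjusted p ran from 1.69e-10 to 0.338 for fatty acid and glucose genes, 1.05e-10 to 0.338 for beta-adrenergic genes and 7.50e-05 to 0.632 for the cAMP list. Of the gained regions, 5.66% lay within 1 kb of a gene end, against 23.1% of the regions present in all 4 libraries (odds ratio 0.486 within height strata, 0.426 to 0.555, adjusted p = 1.45e-26). Regions between genes were enriched among gained ones (odds ratio 1.19, adjusted p = 5.18e-07; 0.953 set against lost regions, where it did not pass). Among lost regions the odds ratio between genes was 1.18 (adjusted p = 0.0366), a call that ended under 9 of 12 alternatives, among them leaving out either vehicle control or either stimulated control library.

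Stimulated H2A.Z knockdown against stimulated control addresses what loss of this histone variant does to accessibility under stimulation; no knockdown under vehicle was part of the series. Regions of thermogenic genes as a list sat slightly lower with knockdown and those of interferon genes higher. Both camera calls were lost with an estimated correlation (adjusted p = 0.987 for each, as for every list, and unadjusted p = 0.137 and 0.136). No single region passed the test. At the start of Ucp1 the height was 232.8 ± 26.4 with knockdown against 303.3 ± 54.2 (log2 change −0.37, SE 0.18). The 3 regions upstream stood at −0.37, −0.44 and −0.22, all 4 with an adjusted p of 1 in limma. At Rtp4, an interferon-induced chaperone of membrane receptors, the height was 124.2 ± 49.9 against 48.5 ± 16.1 (chromosome 16, 23609660 to 23610380; log2 change 1.34, SE 0.26). Its unadjusted p in limma, 3.8e-05, was the smallest of all regions. limma called 0 of 47471 regions, and 1667 had an unadjusted p below 0.05. That share is below the 0.05 that no change would give. The fit pools the spread over the groups, whose SDs of log2 height were 0.293 (vehicle control), 0.184 (stimulated control) and 0.197 (knockdown). With only the 4 libraries compared, limma gave 5372 of 63065 regions an unadjusted p below 0.05. For both first against both second replicates it gave 6027. It called 1 region without vehicle control replicate 1, 3 without vehicle control replicate 2, 1 with absent peaks set to 16 and 7 with only the 4 libraries compared. The Rtp4 region was among them each time (log2 changes of 1.32 to 1.34, adjusted p = 0.00104 to 0.00554). Heights were also simulated from each region's mean and shuffled differences between replicates, with known changes added to 50 regions per size. In these limma recovered 4% of 1.5-fold, 64% of 2-fold and all of the 4-fold and 8-fold changes. Shuffling removed differences that many regions of a library share, so this recovery may be too favourable. Small changes at single regions were thus not detectable at this number of libraries.

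After Rtp4, the smallest p-values with knockdown belonged to regions nearest to Dst, a cytoskeletal linker (log2 change 1.14), Cbfa2t2, a transcriptional corepressor (1.10), Polr1a, the large subunit of RNA polymerase I (1.07), and Ripor2 (1.18). Runx2, a transcription factor of bone cells (0.94), Gng3 (−0.67), Mapk1, the kinase ERK2 (1.06), and regions with no gene within 50 kb (0.69 and 0.88) completed the 10. None passed, each with an adjusted p of 1, although with only the 4 libraries compared the Dst region (1.12) and 1 of those with no gene within 50 kb (0.86) did (adjusted p = 0.0474 for each). The Polr1a region, 10.6 kb from the gene, had fallen on stimulation (−1.04, adjusted p = 0.00465). It stood at −0.64 with the heights as deposited and at −0.87 without stimulated control replicate 1, and did not pass in either case. H2az1 and H2az2, the genes that encode H2A.Z, kept their gene-end peaks in all 6 libraries, with knockdown values of −0.00 and −0.11, which says nothing about their transcript.

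The 140 regions of thermogenic and brown identity genes had a median change of −0.093 with knockdown. Camera put the list below other regions (adjusted p = 0.00061; adjusted p = 0.987 with an estimated correlation). Its members with the largest values were regions nearest to Pparg (−0.77), Kcnk3 (−0.65), the cytochrome oxidase gene Cox8b (−0.60), Ppara (−0.53), Ppargc1b (−0.48), Ebf2, a brown adipocyte determinant (−0.40), and Cpt1b (−0.37), with Acot11 at 0.59 and Esrrg at 0.49. Counted once per gene the list had a mean of −0.084 with 3 of 22 genes above 0 (two-sided permutation test, adjusted p = 0.0137). Fatty acid and glucose genes had a median of −0.081 (adjusted p = 0.00534) and a mean per gene of −0.097 with 5 of 19 above 0 (adjusted p = 0.00435). Beta-adrenergic and lipolysis genes had −0.064 (adjusted p = 0.0192) and −0.075 with 2 of 22 above 0 (adjusted p = 0.0254). The median of the thermogenic list was −0.14 without stimulated control replicate 2, and those of the fatty acid and beta-adrenergic lists were −0.14 and −0.12. Neither of the latter camera calls held without stimulated control replicate 1 (medians −0.047 and −0.058) or without knockdown replicate 2 (medians −0.096 and −0.055). Both had an adjusted p = 0.987 in camera with an estimated correlation. White and general adipocyte genes had a median of −0.080 (adjusted p = 0.0183; 0.443 without stimulated control replicate 2, 0.256 without knockdown replicate 1, where the median was −0.048 (−0.12 without knockdown replicate 2), 0.0730 with absent peaks set to 16, 0.987 with an estimated correlation) and a mean per gene of −0.063 that did not pass (adjusted p = 0.127). No region of these lists was called by limma, over all regions or adjusted over the list alone.

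Interferon genes, which cells switch on against viruses, had a median of 0.098 over 27 regions with knockdown (camera adjusted p = 0.00155; adjusted p = 0.987 with an estimated correlation). Values were 0.91 at Isg15, a ubiquitin-like modifier, 0.75 at Ifit1 and 0.60 at Ifit3, which block viral RNA, 0.59 at Ifih1 and 0.52 at Ddx58, the sensors MDA5 and RIG-I, 0.35 at Usp18 and −0.45 at Rsad2. The mean per gene was 0.25, with 11 of 14 genes above 0 (two-sided permutation test, adjusted p = 0.0006). The camera call ended without stimulated control replicate 1 (median 0.094, adjusted p = 0.0573), without knockdown replicate 2 (median 0.053, adjusted p = 0.614) and among regions of mean height above 64 (adjusted p = 0.0787). Without knockdown replicate 1 the median was 0.22. The other 10 lists did not pass camera, with adjusted p-values given in parentheses. Medians were −0.086 for lipogenesis and creatine cycling (0.0763; past the threshold at 0.00548 with absent peaks set to 16, and at 0.0258, 0.0337 and 0.0243 without vehicle control replicate 2, stimulated control replicate 2 or knockdown replicate 1), −0.011 for the cAMP list (0.958), 0.0087 for preadipocyte and fibroblast genes (0.522) and 0.012 for circadian and nuclear receptor genes (0.699). They were −0.0072 for H2A.Z, chaperones and chromatin architecture (0.958), −0.013 for p53 and stress (0.962) and 0.013 for cell cycle (0.958). Housekeeping genes had −0.0051, immune cell genes 0.041 and skeletal muscle genes 0.031 (0.958 for each). For every list limma called 0 regions with knockdown, over all regions and adjusted over the list alone, where 1667 of all regions had an unadjusted p below 0.05.

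By presence, 1875 regions were gained and 1205 lost with knockdown. The tallest gained region was nearest to Rpe65 (38.2 and 45.2 in the knockdown libraries), followed by Zfp618 (83.4 kb away), Stip1, a heat shock co-chaperone, and Foxd1 (121.5 kb away). The tallest lost region was nearest to Ncoa7 (29.7 and 32.1 in the stimulated control libraries), followed by Epha8, an ephrin receptor, and Tmod2. Lost regions included 10 nearest to 8 thermogenic genes, namely Fgf21, Kcnk3, Ppargc1b, Zfp516, Pparg, Cebpa, Cidea and Acot11 (odds ratio 3.92, 95% interval 1.82 to 8.42, adjusted p = 0.0199, two-sided exact test). With 1 region taken per gene, the peaks at all 8 genes were low, from 16.5 at Kcnk3 to 30.3 at Ppargc1b. Those closest to the lowest reported height of about 16 were 16.6 and 17.9 at Fgf21 and 17.1 and 16.5 at Kcnk3. Other regions of Kcnk3, Pparg and Prdm16 were gained with knockdown. The call for lost regions of thermogenic genes ended under 8 of 13 alternatives. Among them were leaving out stimulated control replicate 1 (2.06) or knockdown replicate 1 (1.87), the comparison with gained regions (5.22) and genes within 10 kb (4.71). Over all of them the adjusted p ran from 0.000387 to 0.47. Fatty acid and glucose genes, with 9 lost regions, did not pass (2.26, adjusted p = 0.365) but did without stimulated control replicate 2 (5.04, adjusted p = 7.55e-09) and without knockdown replicate 1 (3.49, adjusted p = 0.000925). So did beta-adrenergic genes without stimulated control replicate 2 (2.57, adjusted p = 0.0137) and H2A.Z and chaperone genes without knockdown replicate 1 (4.90, adjusted p = 0.0490). Gained regions lay within 1 kb of a gene end less often than regions present in all 4 libraries (odds ratio 0.722, adjusted p = 0.00605). They lay more often between genes (1.14, adjusted p = 0.0366). Both calls ended with peaks merged within 200 bp (0.761 and 1.10) and without knockdown replicate 1 (0.964 and 1.02). The odds ratio near a gene end was 1.28 for lost regions and did not pass (adjusted p = 0.0535). It passed without stimulated control replicate 1 (1.19, adjusted p = 0.0110) or 2 (1.39, adjusted p = 2.63e-05), with a window of 2.5 kb (1.22, adjusted p = 0.0246) and set against gained regions (1.59, adjusted p = 0.00222). Without height strata the direction turned (0.465, adjusted p = 7.06e-18; 9.96% of lost regions against 19.2%), so neither direction is claimed. Randomised tables gave 1764 ± 33.4 gained regions, fewer than observed (one-sided permutation p = 0.0099, the smallest possible), and 1284 ± 31.6 lost regions, more than observed (p = 0.0198). The excess of gained regions was not particular to knockdown: the second replicates of both groups held 1945 regions that both first replicates lacked, more than the 1875. The counts of gained and lost regions were 3014 and 5467 without stimulated control replicate 1, 5235 and 3043 without stimulated control replicate 2, 4340 and 2764 without knockdown replicate 1, and 6356 and 3220 without knockdown replicate 2. At a height of at least 32 they were 7 and 0.

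The comparisons share the stimulated control, which bears on how far the response to stimulation was kept under knockdown. Among the regions that rose on stimulation, such as Ucp1, Ppargc1a, Fosl1 and Adcy3, the median change was 0.87 on stimulation and −0.022 with knockdown, and 53.9% lay below 0 with knockdown. Regions called neither way had a knockdown median of −0.020 with 55.5% below 0, much the same. Regions that fell, such as Thra and Gnas, had medians of −0.81 and 0.025. Adcy3 stood at 447.9 ± 9.40 with knockdown and Fosl1 at 209.1 ± 11.6, and Thra at 95.7 ± 16.3. The covariance between both changes over regions was −0.0133 (correlation −0.121). A shared control gave −0.0170 (correlation −0.363) in data simulated from the spread between replicates alone, with no effect of stimulation or knockdown. The simulated correlation is no reference for the observed one, since it lacks the variance of the real stimulation change (0.266). With the control libraries split between the comparisons the covariance was 0.0159 one way and −0.00857 the other, so its sign was not settled. Of the 6861 regions gained on stimulation, 4873 (71.0%) were present in both knockdown libraries, among them the region in Mylk (226.9 and 185.4), 1330 in 1 of them and 658 (9.59%) in neither, among them the region near Fgf21. The peaks of that Fgf21 region in stimulated control were close to the lowest reported height of about 16. Randomised tables gave 717 ± 26.3 absent from both, more than observed (one-sided permutation p = 0.0198). These tables mix all 6 libraries, which removes the response to stimulation as well, and held 4008 gained regions in place of 6861. The 717 is thus no expectation for a knockdown without effect. Independent sets would give 122, fewer than observed, but the sets share the stimulated control, which raises the overlap by itself. The count of 658 was 1022 without vehicle control replicate 1, 3558 without stimulated control replicate 1, 2042 without stimulated control replicate 2, 1337 without knockdown replicate 1 and 1309 without knockdown replicate 2. Of the 1136 lost regions, 135 (11.9%) were present in both knockdown libraries, where randomised tables gave 155.

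**Figure D4:**
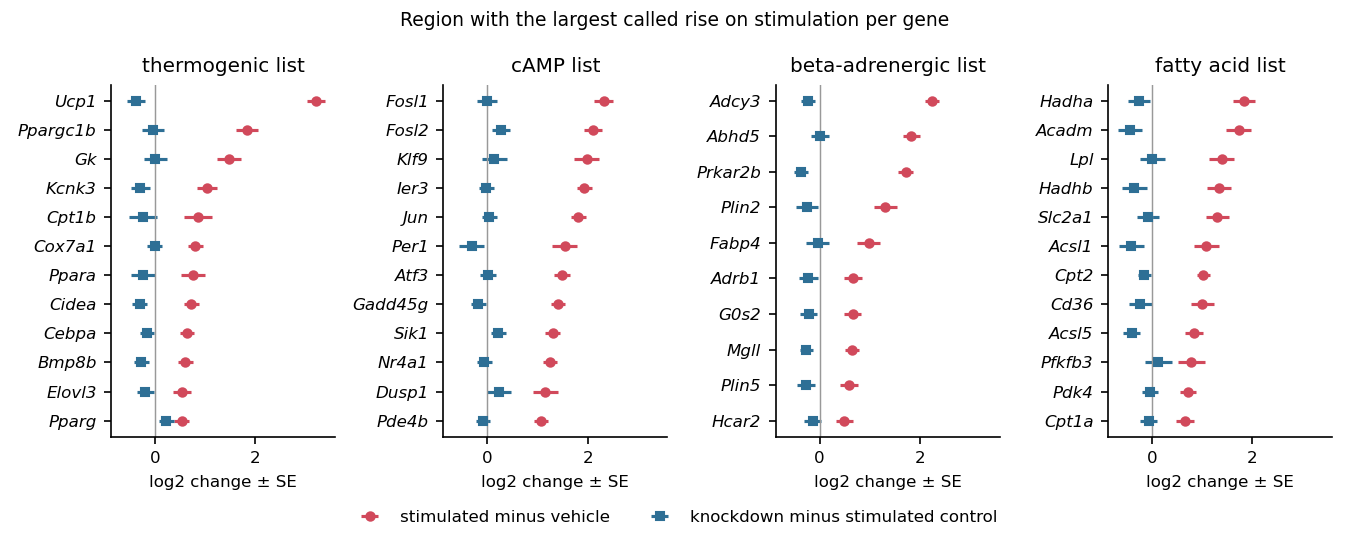
Log2 change in peak height on stimulation (stimulated minus vehicle control) and with knockdown (knockdown minus stimulated control) at the region with the largest called rise of each gene, with SE from limma, for 4 gene lists. Ucp1 reached 3.21 on stimulation and −0.37 with knockdown, and no knockdown value in the plot passed the test.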

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

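The tests by peak height, those with a minimum height of 32 and the genes-as-unit and second-list tests were chosen only after the data were seen; the others were planned. Of 135 alternatives to the 14 results that answer a comparison, 70 stayed within 1.5 times the value or 1 SD and 65 moved. As counts these have no sign, but orders between them turned. With knockdown, gained regions outnumbered lost ones (1875, 1205) except without stimulated control replicate 1 (3014, 5467), in pair 2 (6019, 8671) and at the stricter threshold (424, 433). On stimulation, rises were fewer than falls (4275, 6115) but outnumbered them as deposited (4618, 454), after quantile (5089, 4669) or loess normalisation (4997, 4418), without vehicle control replicate 2 (6165, 4714) and at a mean height above 64 (3584, 3399). Gained and lost regions on stimulation (6861, 1136) became 4162 and 2296 with equal list lengths; the stricter threshold gave 2141 gained, and heights of at least 32 gave 897 and 17, or 4189 and 108 without vehicle control replicate 1 and 1021 and 140 without vehicle control replicate 2. The replicate block gave 10651 and 10418 for pair 1 alone, 27761 and 3955 for pair 2 alone and the counts reported for both pairs. Leaving out 1 library gave 7615 to 18675 gained and 1500 to 5684 lost. With knockdown (1875, 1205), equal lists gave 1123 gained, the stricter threshold 424 and 433, heights of at least 32 gave 7 and 0, and the replicate block 11361 and 5598 for pair 1 and 6019 and 8671 for pair 2; leaving out 1 library gave 3014 to 6356 gained and 2764 to 5467 lost. Regions gained on stimulation and absent with knockdown (658) numbered 423, 177 and 0 under equal lists, the stricter threshold and heights of at least 32, and 707 to 3558 with 1 library left out. Fewer peaks or fewer libraries to match make such counts smaller or larger by construction; beyond that the cause was not tested. Called location tests (5 of 12) became 11 without strata, 8 set against lost regions, 2 with peaks merged within 200 bp, 6 with the replicate block and 2 to 6 without 1 library. With the replicate block, thermogenic (odds ratio 1.77, adjusted p = 0.000387) and lipogenesis genes (1.66, 0.0128) passed among regions gained on stimulation and fatty acid and glucose genes among lost ones (0.505, 0.0302), while the call between genes among lost ones ended (0.996). Among regions lost with knockdown it gave calls for fatty acid and glucose genes (2.30, adjusted p = 1.99e-05), lipogenesis (1.89, 0.0161), preadipocyte genes (0.198, 0.00297), gene ends (1.17, 9.88e-05) and regions between genes (0.921, 0.000518). Called list tests (4 of 60) became 1 without strata, 2 set against lost regions, 2 with equal lists, 2 with merged peaks, 10 with the replicate block, 1 with genes within 10 kb and 3 to 8 without 1 library; the cause was not tested. By height, rises (4275) became 6556 with absent peaks set to 16 and 1798 to 6486 without 1 library; falls (6115) became 454 with heights as deposited, 3399 among regions of mean height above 64, where fewer regions were tested, and 1868 to 11329 without 1 library. The replicate block gave 4839 rises and 7015 falls on stimulation and 0 calls with knockdown. Calls with knockdown (0) became 1 with absent peaks set to 16, 7 with only the 4 libraries compared and 0 to 3 without 1 library; the cause was not tested. Where 1 library was left out of a group, the lone library was assumed to vary like the other groups. On average the libraries of a group shared more than those of different groups (mean Jaccard index 0.787 within, 0.743 between; difference 0.0434, exact permutation p = 0.0667, the smallest possible, highest other pairing 0.0420). This holds for the mean alone: the vehicle control libraries shared 0.699 with each other, where the first shared 0.747 to 0.772 with the other groups, and stimulated control replicate 2 shared 0.841 with knockdown replicate 2 and 0.831 with its own group. By share of regions or equal lists the difference was 0.0453; with the replicate block, between-group pairs of like number differed from others by −0.0022. Peaks per library on every sequence averaged 67013.5, 77769 and 79799.5. For single lists and classes, 602 of 634 alternatives of list tests kept their side of the threshold (13 gained a call, 19 lost it), 394 of 420 by height (6, 20) and 111 of 144 for location (19, 14); over the alternatives at the preset correlation the adjusted camera p ran from 0.00376 to 0.0512 for the cAMP list on stimulation. With knockdown it ran from 9.14e-06 to 0.0103 for thermogenic, 0.0005 to 0.202 for fatty acid, 0.000737 to 0.207 for beta-adrenergic, 0.00719 to 0.443 for white adipocyte and 7.40e-07 to 0.614 for interferon genes. Alternatives of named regions kept their side in 1808 of 1955 on stimulation (19, 128) and 1949 of 1955 with knockdown (6, 0). Motifs and exon and intron classes were not run. The depth of vehicle control replicate 2 limits which weak peaks could be seen there, and 2 libraries per group limit single regions. On stimulation 8% of 1.5-fold and 50% of 2-fold changes were recovered in the simulated heights, with 1 false call.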

Other observations

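The tests chosen only after the result was seen are the ratio of gained to lost regions without vehicle control replicate 2, the second interferon list against random lists, the loess and left-out-library tests of thermogenic genes, the preadipocyte test and both counts of splits; the others were written before their result was seen. Interferon genes beyond the fixed list pointed the same way with knockdown. In a second list of interferon genes that shares no member with the first, 30 of 35 genes lay above 0, with a mean of 0.14 per gene, and p was 2e-05 in a two-sided permutation test, the smallest it can give. On stimulation the second list stood lower, with a mean of −0.23 per gene and 7 of 35 genes above 0. Random lists had a mean of −0.11 there, and the same permutation test gave p = 0.0355. Both comparisons use the stimulated control libraries.

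Nuclear receptor genes other than Thra also held regions that fell on stimulation, although the list of circadian and nuclear receptor genes did not pass. Falls were called at Rxrg, a retinoid X receptor (log2 change −1.31, adjusted p = 0.00157), Ppard, a fatty acid receptor (−0.93, adjusted p = 0.00945), and Rxra (−0.74, adjusted p = 0.0145). With the heights as deposited these were −0.92, −0.53 and −0.34 and did not pass; Rxrg and Rxra did not pass without stimulated control replicate 1 (−1.05 and −0.46), nor Ppard without stimulated control replicate 2 (−0.64).

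More regions were gained than lost on stimulation, 6861 against 1136. The depth of vehicle control replicate 2 may account for this excess: without that library the ratio was 1.34, and 1 library of each group of like depth, the first of each, gave 10651 gained and 10418 lost, a ratio of 1.02. For regions at least 32 high the ratio was 7.29 without that library, above the bound of 4 set beforehand against depth as the cause; it stays open because the first libraries alone gave 2.24, a comparison added afterwards, and stimulated control replicate 2 is deeper than the remaining vehicle library. A biological opening of more regions than closing under stimulation also stays open.

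Interferon-gene regions stood higher with knockdown, a camera call that ended with an estimated correlation (adjusted p = 0.987). The second list, with a permutation p of 2e-05, argues against a chance choice of genes only as far as genes vary independently, which that test assumes. Whether 1 library carries it stays open: at least 23 of the 35 genes lay above 0 in each of the 4 pairs of a knockdown and a stimulated control library, where 24 had been set beforehand as the bound. The mean changes were higher for knockdown replicate 2 (0.22 and 0.15) than for replicate 1 (0.13 and 0.065). For the first list they were 0.42 and 0.32 for knockdown replicate 2, with 13 of 14 genes above 0 in each pair. For knockdown replicate 1 they were 0.18 and 0.076, with 9 of 14 genes above 0. The other splits of the 4 libraries gave the second list at most 0.0756 against 0.14, too few splits for a share under 0.05. For the first list another split reached an absolute mean of 0.17 against 0.25. The comparisons share the stimulated control. On stimulation the first list had a mean per gene of −0.27 (4 of 14 genes above 0) and the second −0.23 (7 of 35), where random lists gave −0.11. Low values in the stimulated control libraries could thus also give higher values with knockdown. An effect of the knockdown, of the particular shRNA or of the lentivirus load could each do so too, and no test here separates them.

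Thermogenic-gene regions stood slightly lower with knockdown. A height-dependent difference between libraries is argued against by a median of −0.0794 after loess normalisation, and 1 library alone by a median of −0.0772 at its closest to 0 with 1 library left out, both still called by camera at the preset correlation (with an estimated correlation the list had an adjusted p = 0.987). The other splits of the 4 libraries gave at most 0.0352 per gene against −0.084, too few splits for a share under 0.05. A smaller share of differentiated adipocytes in the knockdown cultures may contribute. White and general adipocyte genes were lower too (−0.080), but that list shares Pparg and Cebpa with the thermogenic list, so the lists are not separate. Preadipocyte genes, at 0.0087, did not pass, and that leaves this explanation open. The comparisons share the stimulated control. On stimulation the thermogenic list had a mean per gene of 0.082, where random lists gave −0.10. High values in the stimulated control libraries could thus also give lower values with knockdown. A biological effect of H2A.Z on thermogenic-gene regions stays open as well.

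With 4 libraries there are 3 splits into pairs, too few for a share under 0.05. By height, limma called 9106 regions on stimulation for the real split, which 1 of 3 splits reached, and the highest other split gave 0 calls, with 119 regions at an unadjusted p below 0.05. With knockdown the real split gave 7 calls and the highest other split 19, so 2 of 3 splits gave as many. The split with 19 sets both first replicates against both second replicates.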
